A study of Mus musculus with 16 samples.

How the data were processed

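The series measured RNA in cells of the mouse coronal suture on a whole-transcript Affymetrix array, with 16 arrays. Per the labels' protocols, cells came from 2 litters of mixed wild-type and Twist1+/- C57BL6 mice and were kept apart by sex and genotype. Each genotype, sex and day had 3 wells of a 6 well plate in control medium and 3 wells with thyroxine, and 100 ng of total RNA was labelled per array. Whether the wells of a condition were pooled is not given in the sources used here.

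The deposited values are log2 expression values per probe set, made by the authors with the RMA method in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, sets all arrays to the same distribution and summarises the probes of a probe set. Versions, genome build and annotation release are not given in the sources used here. The values ran from 0.57 to 14.05 and the array medians from 3.73 to 3.86. Because RMA equalises the arrays, a shift of all genes in a sample could not be seen, and close to the background differences are compressed.

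The table held 41345 probe sets. The platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010, and only the first kind was named. Entrez identifiers matched 23328 of the named probe sets to current symbols, of which 0 changed. Of the 22180 genes the brightest probe set was used, and the 13453 genes with a mean of at least 3.905, the 40th percentile of named probe sets, were tested. The other 8727 were left out. Some genes of the fixed lists are not analysed here.

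Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with statmod 1.5.0 for random blocks, and Benjamini-Hochberg adjustment at 0.05. For thyroxine, the pair of a control and a thyroxine array of the same genotype, sex and day was a fixed block, with a separate effect for each genotype and day. The pairing comes from the labels, which put both media of a genotype, sex and time on a plate. Across genes, the male minus female differences of control and thyroxine arrays correlated at 0.119 and 0.393 in Twist1+/- cells at 3 and 7 days and at 0.771 and 0.721 in wild-type cells. For genotype, day and sex, the fit had the 8 group means and sex, with the culture as a random block and a within-culture correlation of 0.202. Residual degrees of freedom were 4 in the pair fit and 7 in the group fit, with prior degrees of freedom of 9.30 and 5.11. There was 1 culture for each genotype and sex, so no p-value measures the spread between animals. In the pair fit p-values measure the spread of the pair differences, since the pair block takes up the differences between cultures. In the group fit they rest mainly on the spread between arrays. The same within-culture correlation was set there for every gene, in place of a spread between cultures measured per gene. Both spreads may be technical in part. Genotype and sex rest on 2 cultures against 2.

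Gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says that a gene, comparison or alternative was chosen afterwards. The 22 lists cover thyroid hormone handling and response, bone, suture, mesenchymal, cartilage and adipocyte genes, signalling pathways, extracellular matrix, cell cycle, stress, interferon, cholesterol synthesis, markers of other cell types and sex-linked genes. Lists were tested with camera, with its preset correlation of 0.01 and with an estimated correlation, in the group fit without the random block, and adjusted within a comparison. Of 25 list calls with the preset correlation, 0 were left with an estimated correlation. Named genes were up to 10 per direction with the largest change among those past the threshold and of the same sign in every pair or culture, up to 4 per list, 7 thyroid and genotype genes for thyroxine and genotype and 5 sex-linked genes for sex. Where fewer than 10 genes passed, the 5 higher and 5 lower genes with the smallest p were named as values. Gene models without a characterised name were left out.

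The fits were tested on simulated data with the spread of the real genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 13453. The simulated genes varied independently, and culture effects had the same size in all cultures, unlike the real arrays, where the wild-type male culture stood apart. The rates below hold for those settings and need not hold for the real arrays. For thyroxine over all pairs 79% and 98% were recovered, for wild type 27% and 94%, for Twist1+/- 20% and 96%, for the genotype difference 2% and 56%, for the day difference 2% and 62%, for genotype 32% and 93%, for day 35% and 93% and for sex 67% and 98%. False calls were 15 of 192, 4 of 125, 8 of 124, 6 of 64, 4 of 68, 11 of 136, 4 of 132 and 37 of 202 in that order, with the largest share for sex. Exact sign-flip and permutation tests used the 8 pair differences and took them as independent, although each culture supplied a pair at both days. Alternatives covered the brightness filter, the trend and a robust fit, cyclic loess and median centring, the mean of a gene's probe sets, array weights, a fold limit of 1.5, the blocks, and leaving out each array or pair. Figures were drawn with matplotlib 3.10.9.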

Results

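RNA levels were measured on 16 Affymetrix whole-transcript arrays in cells grown from the coronal suture, the fibrous joint between the frontal and parietal bones of the mouse skull. The mice were C57BL6, either wild type or heterozygous for Twist1, which encodes a basic helix-loop-helix transcription factor of mesenchymal cells. Loss of a copy of this gene causes premature fusion of the coronal suture. Cells were kept in control medium or in medium with thyroxine, the main hormone released by the thyroid gland, at a log10 concentration of -6 mol per liter. RNA was taken after 3 or 7 days, which gave 8 groups of genotype, medium and day. Each group held 2 arrays, 1 from female and 1 from male cells. The series therefore drew on 4 cultures, 1 for each genotype and sex, and on 8 pairs of a control and a thyroxine array of the same culture and day. The number of arrays limits the precision. Differences below are on the log2 scale, and 13453 genes were tested.

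The wild-type male arrays stood apart from the rest. The array with the highest correlation was of the same day for 16 of 16 arrays and of the same culture for 11 of 16, or 7 of the 12 outside the wild-type male culture. Uty, a Y-linked gene, averaged 6.28 ± 0.31 (SD, n = 8 arrays) in male and 2.79 ± 0.23 in female samples, and Xist, the RNA that silences an X chromosome, averaged 3.21 ± 0.19 in male and 6.57 ± 0.86 in female samples, so the sex on the labels and these genes matched on all 16 arrays. On the first principal component, 30.1% of the variance, the 4 wild-type male arrays lay between 26.7 and 31.1, while the other 12 lay between -20.8 and 1.95. On the second component, 29.5% of the variance, the other cultures lay between -26.0 and -7.48 at 3 days and between 16.7 and 26.8 at 7 days, while the wild-type male arrays lay between -14.6 and -10.3 at 3 days and at 1.80 and -10.3 at 7 days. Macrophage and osteoclast genes averaged 9.57 in the wild-type male culture at 3 days and 8.35 in the other cultures (difference 1.22, SD of the other 6 arrays 0.30). Extracellular matrix genes averaged 8.92 there at 3 days against 9.86 (difference -0.94, SD 0.15). Female and male arrays of a wild-type group correlated across probe sets at 0.954 to 0.970, and those of a Twist1+/- group at 0.983 to 0.986.

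**Figure D1:**
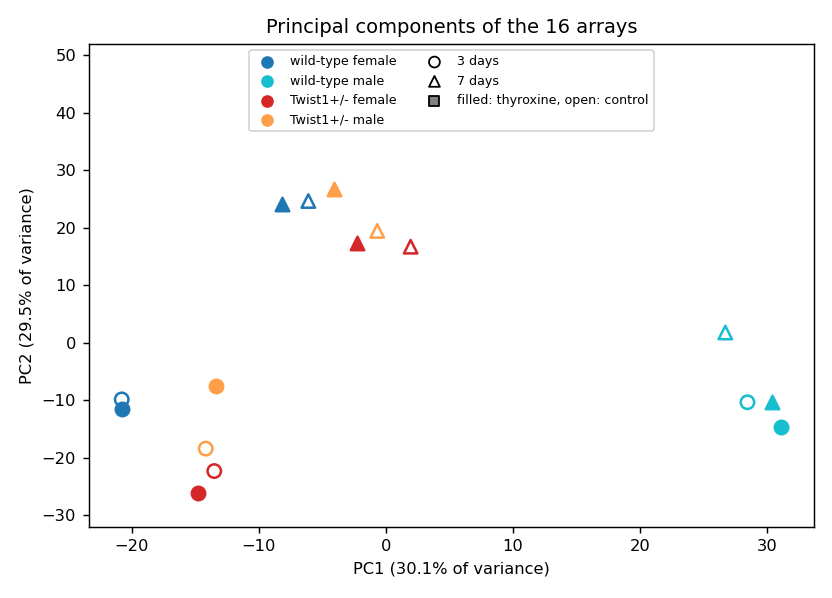
First principal component (x axis) against second (y axis) of the 16 arrays, over all tested genes. Colours mark the 4 cultures, circles 3 days, triangles 7 days, open symbols control and filled symbols thyroxine; the 4 wild-type male arrays lie apart at 26.7 to 31.1 on the first component.

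The first question was what thyroxine did to these cells. Klf9, a Krüppel-like transcription factor directly induced by thyroid hormone receptors, rose by 0.56 ± 0.06 (SE, n = 8 pairs, adjusted p = 0.00458, limma with Benjamini-Hochberg adjustment) and was higher with thyroxine in 8 of 8 pairs, from 7.65 ± 0.22 (SD, n = 8 arrays) to 8.20 ± 0.17. Sfrp4, which encodes a secreted WNT antagonist, rose by 0.67 ± 0.11 (adjusted p = 0.0306). Htra1, a secreted serine protease, rose by 0.57 ± 0.07 (adjusted p = 0.00543), and Npr3, the clearance receptor of natriuretic peptides, rose by 0.40 ± 0.06 (adjusted p = 0.0171). Il6, the cytokine interleukin 6, fell by 0.57 ± 0.07 (adjusted p = 0.00799) in 8 of 8 pairs.

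Stmn2 and Fam180a rose by 0.61 each, Heg1 by 0.49, Mxra7 by 0.40 and Epdr1 by 0.38, all in 8 of 8 pairs and with adjusted p from 0.00782 to 0.0244. In all, 13 genes passed limma's test at an adjusted p under 0.05, 11 higher and 2 lower, and 825 had an unadjusted p under 0.05. In 100 exchanges of the media within pairs, the real arrangement included, some gene reached a t as large as that of Klf9 in 22, of Htra1 in 29, of Il6 in 39, of Npr3 in 47 and of Sfrp4 in 52, and for the other 8 genes in 36 to 56. The remaining genes of the 13 were Igfbp4, which rose by 0.36 but was not higher in every pair, and Ywhag and Rps12-ps24, whose sign differed between pairs. Hr, a nuclear corepressor induced by thyroid hormone, was higher in 8 of 8 pairs by 0.37 ± 0.09 (SE) and did not pass (adjusted p = 0.385). Exact two-sided sign-flip tests over the 8 pairs, run on the 7 genes fixed in advance, gave p = 0.00781 for both Klf9 and Hr, the smallest value that 8 pairs allow, and 0.0273 after adjustment over the 7. These tests took the pairs as independent, although each culture supplied a pair at both days, so they overstate the replication. The same test gave adjusted p from 0.438 to 0.938 for Twist1 (0.01), the receptors Thra (0.11) and Thrb (0.14), and the deiodinases Dio2 (0.06) and Dio3 (0.21).

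Of the thyroid hormone response list, 1 of 13 measured members passed over all genes, and 2, Klf9 and Hr, passed when adjusted over the list alone. The list ranked higher than other genes in limma's camera test with the preset correlation (adjusted p = 0.0257; adjusted p = 0.539 with an estimated correlation). Of the interferon and inflammation list, Il6 alone of 17 members passed over all genes, and 5, Ccl2, Ccl7, Cxcl5, Il6 and Ptgs2, passed when adjusted over the list alone, all lower. Camera ranked that list lower (adjusted p = 0.00382; adjusted p = 0.539 with an estimated correlation). In the WNT list, 1 of 20 members passed over all genes, Sfrp4, and 2 when adjusted over the list alone, Sfrp4 and Nkd1. No call among the 13 was left when the trend of the variance with brightness was not modelled, when the pair block was left out, or when the Twist1+/- pairs at 7 days were left out (0 genes each, with 838, 307 and 452 at an unadjusted p under 0.05). Without the wild-type male culture 1 gene, Pgm5, passed and 0 of the 13 did (685 at an unadjusted p under 0.05). Without the 7-day Twist1+/- pairs 12 of the 13 had the same sign, with Klf9 at 0.50 ± 0.07 (SE), Htra1 at 0.61 ± 0.08 and Il6 at -0.57 ± 0.09, while Ywhag turned and Rps12-ps24 went from -0.89 to -0.28. Without the wild-type male culture all 13 kept their sign, with Klf9 at 0.51, Htra1 at 0.635, Sfrp4 at 0.82, Npr3 at 0.33 and Il6 at -0.47. Leaving out a single pair gave between 0 genes, without the wild-type female pair at 3 days, and 29 genes, without either Twist1+/- pair at 3 days.

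**Figure D2:**
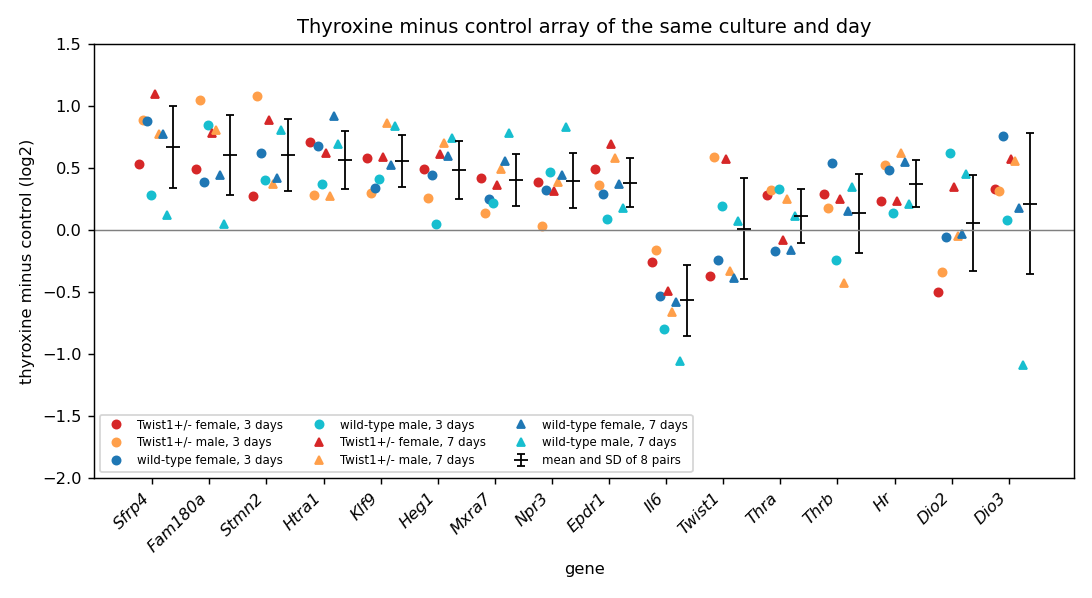
Thyroxine minus control (y axis, log2) for each of the 8 pairs (points) with their mean and SD (bars), for the named genes (x axis). From Sfrp4 to Epdr1 all pairs lie above 0, for Il6 all lie below 0, and for Dio3 the wild-type male pair at 7 days lies at -1.09.

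In wild-type cells, Il6 fell by 0.74 ± 0.10 (SE, n = 4 pairs) and Htra1 rose by 0.67 ± 0.09, both with an adjusted p of 0.0436 from limma and the same sign in 4 of 4 pairs. These were the 2 genes past the threshold, while 752 had an unadjusted p under 0.05. Klf9 was higher by 0.53 ± 0.08 and Npr3 by 0.52 ± 0.08 in 4 of 4 pairs without passing (adjusted p = 0.105 for both). The water channel gene Aqp1 (0.56), Mxra7 (0.45) and Heg1 (0.46) were higher and Rtl3 (-0.60), Cxcl5 (-0.61), Ms4a6b (-0.86), Oser1 (-0.60) and Cd200r4 (-0.56) lower in 4 of 4 pairs, with adjusted p from 0.190 to 0.347. Interferon and inflammation genes were lower with thyroxine in 16 of 17 members, with a median of -0.24. Besides Il6, the interferon-induced Ifit1 (-0.53) and Usp18 (-0.43) and the chemokine genes Ccl2 (-0.29) and Ccl7 (-0.30) were among the 8 that passed when adjusted over the list alone, against 1 over all genes. Camera ranked the list lower (adjusted p = 1.51e-12; adjusted p = 0.432 with an estimated correlation). Macrophage and osteoclast genes, lower in 12 of 15 members with a median of -0.11, were ranked lower as well (adjusted p = 0.0227; adjusted p = 0.560 with an estimated correlation). No member of that list passed, over all genes or adjusted over the list alone. Both single-gene calls were lost under several alternatives, and 0 genes passed without the wild-type male culture (413 at an unadjusted p under 0.05).

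In Twist1+/- cells, Fam180a rose by 0.78 ± 0.13 (SE, n = 4 pairs), Klf9 by 0.58 ± 0.08 (adjusted p = 0.00979, limma), Igfbp4, an insulin-like growth factor binding protein, by 0.53 ± 0.07, Epdr1 by 0.53 ± 0.08 and Heg1 by 0.52 ± 0.09. Pbp2 fell by 0.81 ± 0.14, the glycosyltransferase gene Galnt18 by 0.60 ± 0.11 and the ubiquitin ligase gene Huwe1 by 0.46 ± 0.08. Each of these had the same sign in 4 of 4 pairs and an adjusted p of at most 0.0437. In all, 27 genes passed, 22 higher and 5 lower, with 1397 at an unadjusted p under 0.05. Hr (0.40, adjusted p = 0.346) and Il6 (-0.39, adjusted p = 0.222) did not pass. In the thyroid hormone response list, 1 of 13 members passed over all genes and 3, Bcl3, Hr and Klf9, when adjusted over the list alone.

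The 7-day pairs carried many of the 27 calls. For 19 genes the difference at 3 days, in the called direction, was under 0.5 of that at 7 days, and for 8 it was at least 0.5 of it, among them Mir328 (1.16 and 1.18), Rny3 (0.86 and 0.62) and Fam180a (0.77 and 0.80). Among these genes the median difference in the called direction was 0.16 at 3 days, 1.56 at 7 days and -0.25 in the wild-type pairs at 7 days. Rps18, a ribosomal protein gene, differed by 2.82 and 2.48 in the female and male Twist1+/- pairs at 7 days. It averaged 6.16 on the 2 control arrays of those pairs and 8.56 ± 0.33 (SD) on the 14 other arrays. Ywhag, which encodes a 14-3-3 protein, averaged 6.51 on the same control arrays and 9.04 ± 0.23 on the 14 others. Atp5d, Myl12a, Prss23, Tpt1, Tuba1b, Zfp526 and Tmem202 differed in the same way, by 2.10 to 3.12 at 7 days. Other ribosomal protein genes did not share this: the median over 54 of them was -0.05 in the female and -0.03 in the male pair. Limma called 103 genes at 7 days, 59 higher and 44 lower, and 0 at 3 days (318 at an unadjusted p under 0.05). Without the 7-day pairs no gene passed in Twist1+/- cells (288 at an unadjusted p under 0.05), and leaving out single pairs gave 0 to 232 genes, the lowest without the female pair at 7 days and the highest without the female pair at 3 days.

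**Figure D3:**
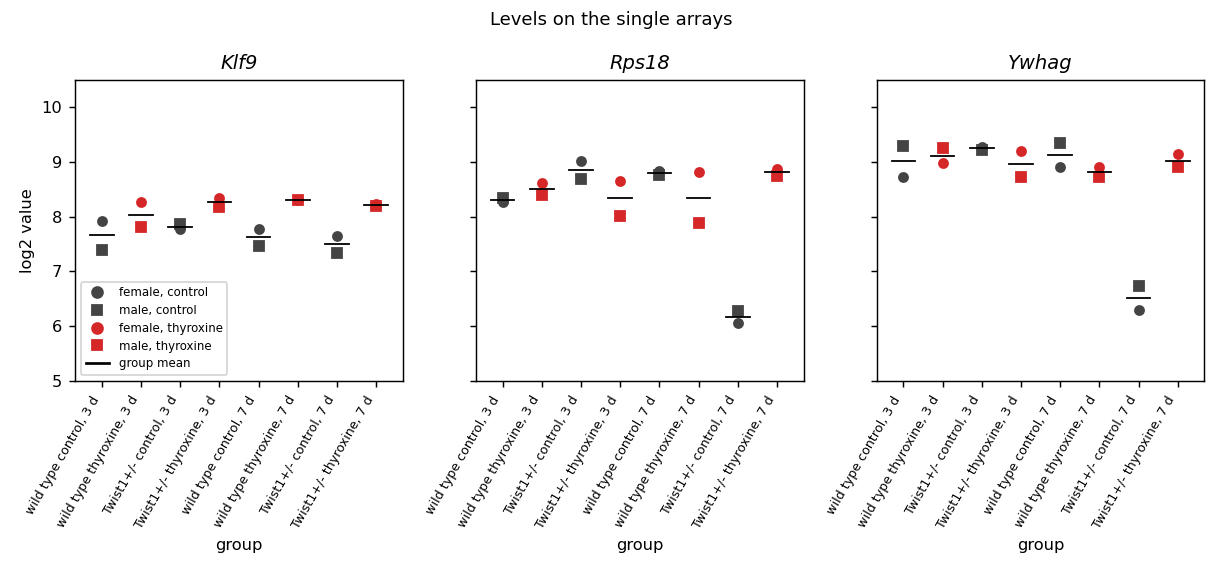
Log2 value (y axis) of Klf9, Rps18 and Ywhag on each array by group (x axis); circles are female, squares male, grey control, red thyroxine, and lines group means. Rps18 and Ywhag lie at 6.16 and 6.51 in the Twist1+/- control group at 7 days and average 8.56 and 9.04 on the 14 other arrays, while Klf9 lies higher with thyroxine at each genotype and day.

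Whether the genotypes differed in their response was tested directly. Tuba1b, an alpha tubulin gene, had an effect larger in Twist1+/- than in wild-type cells by 1.22 ± 0.16 (SE, adjusted p = 0.0193, limma), Rps18 by 1.19 ± 0.17, Ywhag by 1.22 ± 0.17 and Atp5d by 1.59 ± 0.25 (adjusted p = 0.0362). For these 4 genes the Twist1+/- effect lay between 2.10 and 3.12 at 7 days and between -0.52 and -0.21 at 3 days. The other calls were the small RNA genes Snord69 (0.10 at 3 and 1.86 at 7 days in Twist1+/- cells), Snord49a (0.20 and 1.94), Mir328 (1.16 and 1.18) and Rny3 (0.86 and 0.62), of which Mir328 and Rny3 were higher at both days. These 8 genes, all with a larger effect in Twist1+/- cells, were named after their values were seen. The naming rule left out the small RNA genes by their type of name. It left out the other 4 because their pair differences overlapped between the genotypes. At an unadjusted p under 0.05 there were 1282 genes. Further genes with the smallest p did not pass, with adjusted p from 0.0588 to 0.199. The effect, counted with its sign, was higher in Twist1+/- cells for Alox5 (1.09), Rtp4 (0.73), Oser1 (0.92), S100a11 (0.79) and Zfp526 (1.20). It was lower for Galnt18 (-0.86), Pbp2 (-0.94), Huwe1 (-0.53), Rnft1 (-0.51) and Rpl9 (-0.57), of which Galnt18, Pbp2 and Huwe1 fell in Twist1+/- cells. Klf9 (0.06 ± 0.12, adjusted p = 0.907), Hr (0.06 ± 0.19, adjusted p = 0.946) and Il6 (0.35 ± 0.14, adjusted p = 0.484) did not pass the test of the difference. Across genes, which are not independent replicates, the effects in the genotypes correlated at r = -0.109 (Spearman's rho = -0.119).

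The interferon and inflammation list was also compared between the genotypes. Its mean difference was -0.27 and -0.15 in the female and male wild-type pairs at 3 days and -0.10 and -0.60 at 7 days, against 0.05 to 0.12 in the 4 Twist1+/- pairs. Of these, the female pair at 7 days had a median of -0.06 with 9 of 17 members lower, and Il6 was lower with thyroxine in all pairs of both genotypes. The effect, counted with its sign, was higher in Twist1+/- cells for 16 of 17 members, with a median difference of 0.36. The list mean fell by 0.28 in wild-type cells and was 0.07 higher with thyroxine in Twist1+/- cells. Of the members 6, Ccl5, Cxcl5, Ifit1, Ifit3, Oasl2 and Usp18, passed when adjusted over the list alone, against 0 over all genes. Camera ranked the list higher (adjusted p = 9.57e-09; adjusted p = 0.766 with an estimated correlation). An exact two-sided permutation test of the 8 pair means, added after the values were seen, gave p = 0.0286, the smallest that 4 against 4 pairs allow, and 0.30 after adjustment over 21 lists. The cartilage list (difference -0.12) gave the same 2 values. The test took the pairs as independent, although genotype differed only between cultures, 2 against 2, each with a pair at both days. All 8 gene calls were lost without the Twist1+/- pairs at 7 days, where the genotype difference was that at 3 days alone (549 genes at an unadjusted p under 0.05). They were also lost without the wild-type male culture (513 genes).

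The thyroxine effect was also compared between days. Rps18 alone passed, with an effect larger at 7 than at 3 days by 1.26 ± 0.17 (SE, n = 8 pairs, adjusted p = 0.0491, limma), and 724 genes had an unadjusted p under 0.05. Ywhag (1.19), Myl12a (1.26), Tuba1b (0.93), Atp5d (1.42) and the cornified envelope gene Lce1h (1.47) had higher effects at 7 days, counted with their sign, without passing. The macrophage receptor genes Siglec1 (-0.60) and Tlr8 (-0.58) and the genes Tspan14 (-0.44), Rnft1 (-0.47) and Nipal1 (-0.60) had lower effects at 7 days, counted with their sign. Their adjusted p ran from 0.430 to 0.662. Klf9 differed by 0.29 ± 0.12 between days (adjusted p = 0.896). With the Twist1+/- pairs at 7 days left out, the day difference was that of wild-type cells alone. There 0 genes passed and 595 had an unadjusted p under 0.05.

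The genotypes were compared in control medium. Twist1 averaged 7.08 ± 0.46 (SD, n = 4 arrays) in Twist1+/- and 6.87 ± 0.78 in wild-type cells, a difference of 0.21 ± 0.34 (SE, adjusted p = 0.943, limma). Over both media its level lay between 6.07 and 7.70 on the wild-type and between 6.51 and 7.55 on the Twist1+/- arrays. By culture it averaged 7.37 ± 0.30 (SD, n = 4 arrays) in wild-type female, 6.28 ± 0.21 in wild-type male, 6.97 ± 0.35 in Twist1+/- female and 7.31 ± 0.29 in Twist1+/- male cells. The sources used here do not give the part of the gene altered in the mutant allele, so its level does not check the genotype labels. No gene passed limma's test, with 639 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.417. At 7 days alone, a comparison chosen after the data were seen, 7 genes passed, all lower in Twist1+/- cells: Rps18 (-2.64, adjusted p = 0.00119), Ywhag (-2.62), Atp5d (-3.06), Myl12a (-2.37), Zfp526 (-2.18), Tpt1 (-2.08) and Tmem202 (-2.30), all among the genes low on those 2 control arrays. At 3 days alone 0 passed (530 at an unadjusted p under 0.05). Of the genes with the smallest p over both days, the citrate transporter gene Slc13a5 (1.11), Pappa, which encodes a protease of insulin-like growth factor binding proteins (0.74), Sema3d (0.85), Sytl2 (0.61) and Ehd3 (0.60) were higher in Twist1+/- cells in 4 of 4 comparisons of the same sex and day. Ywhag (-1.19), Rps18 (-1.04), Atp5d (-1.44), Erdr1 (-0.45) and S100a11 (-0.59) were lower, Erdr1 in 4 of 4, Rps18 in 2 of 4 and the other 3 genes in 3 of 4 comparisons.

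As groups, macrophage and osteoclast genes were lower in Twist1+/- cells for 13 of 15 members, with a median of -0.55 (camera adjusted p = 8.32e-06; adjusted p = 0.686 with an estimated correlation). Extracellular matrix genes were higher for 21 of 23, with a median of 0.33 (adjusted p = 0.0248; adjusted p = 0.686 with an estimated correlation), and craniosynostosis and suture genes for 20 of 24, with a median of 0.16 (adjusted p = 0.0490; adjusted p = 0.559 with an estimated correlation). WNT genes were higher for 17 of 20 (adjusted p = 0.0319) and cell cycle genes lower for 19 of 23 (adjusted p = 0.00911), both with an adjusted p of 0.686 with an estimated correlation. In these 5 lists 0 members passed over all genes and 0 when adjusted over the list alone. The wild-type male culture, apart on the first component, is 1 of the 2 wild-type cultures and carried most of these differences. Against the wild-type female culture alone, a comparison chosen after the data were seen, the 2 Twist1+/- cultures had a median of -0.08 for extracellular matrix genes (14 of 23 lower) and 0.09 for cell cycle genes (17 of 23 higher), both turned in sign, and of -0.06 for macrophage and osteoclast (9 of 15 lower), 0.03 for WNT (11 of 20 higher) and 0.05 for craniosynostosis and suture genes (14 of 24 higher). That comparison mixes sex with genotype, since 1 of the 2 Twist1+/- cultures is male. Between the female cultures the median was -0.20 for extracellular matrix genes (16 of 23 lower) and -0.005 for cell cycle genes (12 of 23 lower). It was -0.115 for macrophage and osteoclast (13 of 15 lower), 0.04 for WNT (12 of 20 higher) and 0.06 for craniosynostosis and suture genes (14 of 24 higher). A fit without the wild-type male culture, chosen after the data were seen, in effect set the female Twist1+/- level against the wild-type female culture, with no culture block. The genes it called are not named, since they cannot tell genotype from a difference between cultures.

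From 3 to 7 days in control medium, the genes called included macrophage genes that rose and genes of cholesterol synthesis and of contractile fibres that fell. C1qa, a complement component made by macrophages, rose by 1.48 ± 0.24 (SE, adjusted p = 0.00555, limma), from 8.82 ± 0.70 (SD, n = 4 arrays) to 10.30 ± 0.24. The endosomal receptor gene Tlr8 rose by 2.06 ± 0.25 and the sialic acid receptor gene Siglec1 by 1.83 ± 0.23 (adjusted p = 0.00312 for both). Sqle, a rate-limiting enzyme of cholesterol synthesis, fell by 0.89 ± 0.16 (adjusted p = 0.00716), from 7.77 ± 0.11 to 6.88 ± 0.31. Cnn1, the smooth muscle protein calponin 1, fell by 1.07 ± 0.26 (adjusted p = 0.0254). In all 1071 genes passed, 739 higher and 332 lower at 7 days, and 2975 had an unadjusted p under 0.05.

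The genes that rose most, with the same sign in both sexes and both genotypes, were Nxpe5 (2.43), Tlr8, Fcrls (2.00), Hpgd (2.00), Wfdc17 (1.87), Siglec1, Ms4a14 (1.80), Cd33 (1.79), Ms4a6d (1.79) and Cd84 (1.76). Those that fell most were Myl12a (-1.64), Nme1 (-1.24), Coch (-1.24), Sema7a (-1.18), Cnn1, Rgs4 (-1.01), Slc13a5 (-0.99), the filamin gene Flnc (-0.92), Amot (-0.91) and Actg2 (-0.91). Of these, Myl12a was also among the genes low on the Twist1+/- control arrays at 7 days.

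In the macrophage and osteoclast list 12 of 15 measured members passed, all higher, and 13 did when adjusted over the list alone. C1qc (1.47), Ptprc (1.26) and Lyz2 (0.90) were among them, while the osteoclast genes Acp5 (-0.19) and Ctsk (-0.17) did not pass. The list's median was 1.26 and camera ranked it higher (adjusted p = 9.28e-11; adjusted p = 0.276 with an estimated correlation). Its mean rose by 1.58 in the Twist1+/- female, 1.14 in the Twist1+/- male and 1.34 in the wild-type female culture, and by 0.16 in the wild-type male culture, over both media. In the cholesterol synthesis list 5 of 11 members passed, all lower, and 9 did when adjusted over the list alone, with all 11 below 0 and a median of -0.56. Besides Sqle these included Hmgcs1 (-0.88), Cyp51 (-0.78) and Sc5d (-0.56). Camera ranked the list lower (adjusted p = 1.23e-06; adjusted p = 0.334 with an estimated correlation). In the smooth muscle and myofibroblast list 5 of 11 members passed, all lower, with Lmod1 (-0.82), Myl9 (-0.64) and Acta2 (-0.42) beside Cnn1, and 6 did when adjusted over the list alone (camera adjusted p = 0.000368; adjusted p = 0.367 with an estimated correlation). In the cell cycle list 2 of 23 passed, Mki67 (-0.62) and Birc5 (-0.52), and 7 when adjusted over the list alone, all lower (camera adjusted p = 0.000254; adjusted p = 0.407 with an estimated correlation).

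**Figure D4:**
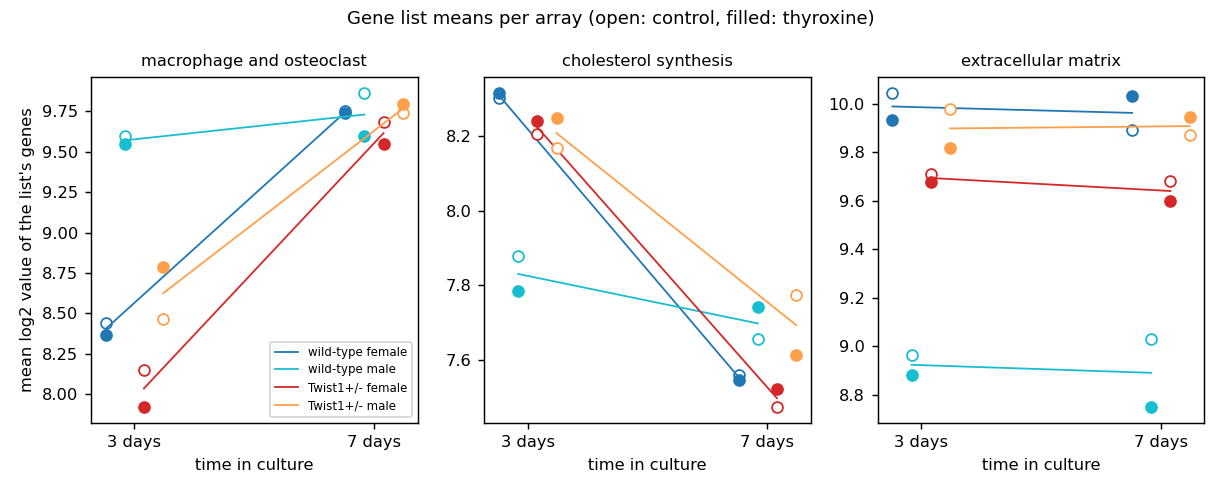
Mean log2 value of the genes of 3 lists (y axis) on each array at 3 and 7 days (x axis), by culture (colour); open symbols are control, filled symbols thyroxine, and lines join culture means. At 3 days the wild-type male culture averages 9.57 for macrophage genes against 8.35 in the other cultures, and its extracellular matrix mean lies lower at both days.

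Other lists held fewer calls. In the neural and Schwann list 2 of 6 passed, Ncam1 (-0.77) and Nes (-0.55), also when adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.276 with an estimated correlation). In the craniosynostosis and suture list 4 of 24 passed, Tgfbr1 higher (0.83) and Fgfr2 (-0.65), Zic1 (-0.47) and Efnb1 (-0.42) lower, and 4 when adjusted over the list alone (camera adjusted p = 0.0468; adjusted p = 0.276 with an estimated correlation). Of BMP and TGF-beta genes 4 of 25 passed, all higher, with Tgfbr1, Tgfbi (0.73) and Tgfb1 (0.71), and 8, 4 higher and 4 lower, when adjusted over the list alone. Of FGF genes 3 of 15 passed, Dusp6 (0.66) and Spred1 (0.46) higher and Fgfr2 lower, and 3 when adjusted over the list alone. Of extracellular matrix genes 3 of 23 passed, Mmp3 higher (1.58) and Tnc (-0.76) and Col5a2 (-0.81) lower, and 7 when adjusted over the list alone. Of Twist1 partners and mesenchymal factors 2 of 19 passed, Snai1 (-0.59) and Id2 (0.56), and of the thyroid hormone response list 2 of 13, Igf1 (1.11) and Me1 (-0.36), with the same counts when adjusted over the list alone. A single member passed in the lists of thyroid hormone handling (Slc7a8, 1.09), WNT signalling (Sfrp2, 0.79), adipocytes (Fasn, -0.65), endothelium (Vwf, 0.46), epithelium (Cdh1, 0.44) and stress response (Atf3, 0.66). When adjusted over the list alone the adipocyte list held 3 and the other 5 held 1 each. The lists of osteoblast (8 members), cartilage (8), skeletal muscle (10) and interferon genes (17) held 0 over all genes and, in that order, 0, 1, 0 and 0 when adjusted over the list alone. Camera gave an adjusted p of at least 0.0942 for the lists without a camera value here.

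The day effect differed in size between cultures. Over the 1071 genes the median change in the called direction was 0.74 in the Twist1+/- female, 0.67 in the Twist1+/- male, 0.63 in the wild-type female and 0.19 in the wild-type male culture, over both media. Limma called 3 genes in wild-type cells alone (Cemip, Jph2 and Stat4, 1602 at an unadjusted p under 0.05) and 856 in Twist1+/- cells alone. The test of the difference called Rps18 (-3.18), Ywhag (-2.85) and Zfp526 (-2.82), the genes low on the Twist1+/- control arrays at 7 days. Leaving out single control arrays gave 181 genes without the wild-type female array at 7 days up to 982 without the wild-type male array at 3 days.

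Males and females differed in 9 genes. Eif2s3y and Uty, both Y-linked, were higher in males by 3.50 ± 0.19 (SE, n = 8 arrays of each sex) and 3.49 ± 0.13 (adjusted p = 4.03e-08, limma), and Xist was lower by -3.35 ± 0.36 (adjusted p = 0.00290). These were all 3 tested members of the list of sex-linked genes, also when adjusted over the list alone. The 6 further genes fell outside the sex chromosome list and were lower in males. They were Igfbp2 (-1.44), Fam180a (-1.28), Elobl (-1.06), the semaphorin gene Sema3d (-1.02), the neurotrophin receptor gene Ngfr (-0.86) and the forkhead gene Foxc1 (-0.75), with adjusted p from 0.0130 to 0.0201. In all, 1307 genes had an unadjusted p under 0.05. Kdm6a (-0.58) and Kdm5c (-0.60), X-linked genes that escape silencing, did not pass (adjusted p = 0.0544 and 0.159), nor did the higher Plau (0.60), Lpl (0.76), Folr2 (1.44), Stat4 (0.59) and Dyrk3 (0.58) or the lower Arsi (-0.78), Bmp4 (-1.07) and Rarres1 (-0.67).

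Cell cycle genes were higher in males for 23 of 23 members, with a median of 0.26, and 7 passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 1.77e-10; adjusted p = 0.179 with an estimated correlation). Macrophage and osteoclast genes were higher for 14 of 15 (camera adjusted p = 2.91e-05; adjusted p = 0.359 with an estimated correlation), and extracellular matrix genes lower for 20 of 23 (camera adjusted p = 6.90e-05; adjusted p = 0.407 with an estimated correlation). Of these lists 2 members, both higher, and 3, of which 1 was higher, passed when adjusted over the list alone. WNT, craniosynostosis and suture, osteoblast, cartilage and stress response genes ranked lower, with camera adjusted p of at most 0.0252, and at least 0.0901 with an estimated correlation. In that order 0, 4, 0, 1 and 0 members passed when adjusted over the list alone, and 0 over all genes. The lower ranks were smaller or turned in sign outside the wild-type male culture. Within Twist1+/- cells, a comparison chosen after the data were seen, extracellular matrix genes were higher in males for 18 of 23 (median 0.17, against -0.91 in wild type), and the medians were 0.07 for osteoblast genes (-0.57 in wild type), 0.02 for stress response genes (-0.28), -0.01 for WNT (-0.24), -0.07 for craniosynostosis and suture (-0.24) and -0.09 for cartilage genes (-0.18). Cell cycle genes were higher in males in both genotypes (0.18 in Twist1+/-, 0.39 in wild type), as were macrophage and osteoclast genes (0.34 and 0.68). With 1 mean per culture, 2 against 2, the 3 sex-linked genes were left. The thyroxine effect did not differ between the sexes for any gene in limma's test (0 genes, smallest adjusted p = 0.493, 488 at an unadjusted p under 0.05).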

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

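The tests of explanations here, and the limits by which the sample exchanges and splits were read, were chosen after the results were seen. The wild-type male culture is weighed under the other observations.

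Dio3, which encodes the deiodinase that inactivates thyroid hormone, had a thyroxine minus control difference of -1.09 in the wild-type male pair at 7 days, far from the 0.08 to 0.76 of the other 7 pairs. The gap to the nearest pair, 0.632 of the whole range, passed a limit that chance passes in about 1 in 20 groups, and 16 genes were examined. The test of the genotype difference in the thyroxine effect called 8 genes, that of the day difference 1 gene, and that of the genotype difference in the day effect in control medium 3 genes. Among the 5646 bright probe sets with no symbol or several, which the comparisons left out, 2 passed for thyroxine in Twist1+/- cells and 62 for the day effect, 31 in each direction.

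Without the 7-day Twist1+/- pairs, no call was left for thyroxine in Twist1+/- cells, for the genotype difference or for the day difference. The first 2 of these were then tested at 3 days alone, and the day difference in wild-type cells alone. Rps18, Ywhag and similar genes were low on the 2 control arrays of the 7-day Twist1+/- pairs. Mir328 (1.16 at 3 and 1.175 at 7 days) and Rny3 (0.865 and 0.625) were higher with thyroxine in Twist1+/- cells at both days, but their calls were lost too. Mir328 lay close to the brightness limit, at 3.085 on these control arrays and 4.26 with thyroxine at 7 days. Over the 27 called genes, a median share of 0.519 (interquartile range 0.561) of the 7-day difference lay between these control arrays and the 12 arrays outside the 7-day Twist1+/- groups, and the shares ran from -1.17 for Rny3 to 1.14 for Prss23, so wide a spread that a departure of the control arrays and a response to thyroxine cannot be told apart over the set. A lower yield of small RNAs on those arrays is argued against for the snoRNA calls in Twist1+/- cells. The lower of the 7-day Twist1+/- medians over 65 snoRNA and scaRNA probe sets was -0.04, under the 0.58 of a 3-day pair. These medians ran from -0.49 to -0.11 in the wild-type pairs and from -0.23 to 0.58 in the Twist1+/- pairs. Whether this bears on the small RNA calls of the genotype difference was not tested. A general change of ribosomal protein genes is argued against for Rps18, since the mean of their medians was -0.04 (SD over genes 0.36). An effect of hybridisation or of the control wells on a limited set of probe sets stays open, as does a biological state of the Twist1+/- control cells at 7 days, because both arrays of that group share it.

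Macrophage genes were higher at 7 days. A loss of the main stromal cells should raise the markers of every other cell type present. Endothelial, skeletal muscle, neural and epithelial markers had a median day effect of -0.10 (SD 0.32, 25 genes), against 1.26 for the macrophage list. This cannot decide the question, because whether those cell types were present was not tested, and markers of absent cells would not rise. A loss of stromal cells therefore stays open. A single culture is argued against, since the list mean rose in all 4 cultures, least in the wild-type male culture, by 0.16. Growth of macrophages within the cultures and induction of these genes in the cells present also stay open, and neither of these was tested.

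Exchanges of the media within pairs, and other splits of the arrays, were used to ask whether chance can be excluded. For thyroxine over all pairs, 18 of 100 exchanges gave at least the real 13 genes and the highest other gave 200, so chance is not excluded for the count. That exchange turned the Twist1+/- male pair at 3 days and both Twist1+/- pairs at 7 days, which points to a structure of those pairs. In wild-type and in Twist1+/- cells the 8 exchanges are too few for a share under 0.05. The real split gave 2 genes and the highest other 0 in wild type (1 of 8 as large), and the real split gave 27 and the highest other 318 in Twist1+/- cells (3 of 8 as large). For the genotype difference in the thyroxine effect, the 8 pairs were set into other groups of 2, and 9 of 100 such splits gave at least the real 8 genes, the highest 75. For the day difference 17 of 100 gave at least the real 1 gene, the highest 35. Chance is not excluded for either count, and both highest splits kept the 7-day Twist1+/- pairs together in a group, which again points to a structure of those pairs. For the genotype in control medium the real count was 0, which each of the 35 of 35 splits reaches by necessity, so the splits decide nothing, and the highest, 162, was the split by day. For the day, the real split gave 162 genes without a block, the highest other 4, and 1 of 35 splits was as large, so chance is excluded if arrays of a culture count as independent. Of these splits, 8 put each culture on both sides, too few for a share under 0.05, and there the highest other gave 0 genes. For sex, the 3 splits of the 4 cultures are too few for a share under 0.05. The real split gave 18 genes without a block, 2 of 3 were as large, and the highest other, 416, set the Twist1+/- female and wild-type male cultures against the rest, a structure of the cultures.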

How the results depend on the processing

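Tests that left out the Twist1+/- pairs at 7 days, the wild-type male culture, a genotype in the day effect or a day in the genotype effect were chosen after the data were seen. The 5 thyroxine counts are given in the order all pairs, wild type, Twist1+/-, genotype difference and day difference (13, 2, 27, 8 and 1). Each fell to 0 when the variance trend was not modelled, with no pair block, and without the 7-day Twist1+/- pairs; with the culture block in place of the pair block they were 3, 0, 1, 0 and 0. Without the wild-type male culture they were 1 (0 of the 13), 0, 26, 0 and 1. The wild-type count was 0 with no brightness filter, cyclic loess or median centring, 4 with array weights and 1 with wild-type arrays alone. The Twist1+/- count was 47 with the mean of a gene's probe sets, where the genotype difference was 5, and a robust fit gave a genotype difference of 2. The day difference was 0 with no brightness filter, the 60th percentile, a robust fit, cyclic loess or the mean of probe sets, and 2 with median centring or array weights. With a fold of at least 1.5 the count over all pairs was 4 and the day effect 584. The genotype effect was 140 without the wild-type male culture, 7 at 7 days alone and 0 under the other settings. The 140 cannot tell genotype from a difference between cultures, since wild type then rests on 1 culture with no culture block. The day effect (1071) was 660 with no culture block, 1725 with culture as a fixed block, 2493 over both media, 1945 without the wild-type male culture and 3 in wild-type arrays alone. The sex effect (9) was 15 with no brightness filter, 0 at the 60th percentile, where the sex-linked genes fell below the limit while Igfbp2, Foxc1 and Ngfr stayed above it and lost their calls, 37 with no culture block, 3 with 1 mean per culture and 224 without the wild-type male culture. The 224 cannot tell sex from a difference between cultures either. That fit in effect set 1 male against 1 female Twist1+/- culture, with arrays as the units and no culture block. The list calls went from 25 to 0 with an estimated correlation. Leaving out a replicate gave 0 to 29, 0 to 9, 0 to 232, 0 to 202 and 0 to 17 for thyroxine, 0 to 0 for genotype, 181 to 982 for day and 3 to 10 for sex; a lone array was then assumed to vary like the other groups. Among the genes called for thyroxine and those named as called for day and sex, the sign turned only without the 7-day Twist1+/- pairs: over all pairs for Ywhag (-0.16); in Twist1+/- cells for Alox5 (-0.10), Atp5d (-0.26), Myl12a (-0.34), Prss23 (-0.29), Rps12-ps24 (0.07), Rps18 (-0.52), Tmem202 (-0.27), Tpt1 (-0.21), Tuba1b (-0.20), Ywhag (-0.28) and Zfp526 (-0.10); in the genotype difference for Atp5d (-0.38), Rps18 (-0.72), Tuba1b (-0.14) and Ywhag (-0.39); and in the day difference for Rps18 (-0.64). Genes named without a call were not followed. Apart from smaller sets of samples or genes, the cause was not tested. Signal close to the background limits what the arrays show for dim genes such as Dio3.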

Other observations

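The tests in this part were chosen after the results were seen, and 977 of the 1778 genes on which the early time course was examined are among the 1071 in which it was noticed.

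The wild-type male culture differed from the other 3 cultures in 3084 of the tested genes, 1376 higher and 1708 lower, with arrays as the units, so this count describes that culture and no population. Extracellular matrix genes were lower in it, 19 of 23 lower and 2 higher past limma's threshold, with a median of -0.84, as were osteoblast and bone matrix genes (6 of 8 lower, median -0.51) and WNT genes (9 of 20 lower). Cell cycle genes were higher (17 of 23, median 0.37), as were macrophage and osteoclast genes (10 of 15, median 0.68). Of interferon and inflammation genes, 10 of 17 were lower and 1 higher.

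A difference between the sexes is argued against as the whole cause, since 2393 genes called between the male and female cultures on the wild-type arrays alone had, in the same direction, a median difference of -0.045 in Twist1+/- cells (interquartile range 0.24) against 0.57 in wild type. A larger share of macrophage-lineage cells is argued against as the whole cause, because at 7 days the macrophage list differed by 0.02 (SD of the other 6 arrays 0.09) while the extracellular matrix list still differed by -0.95 (SD 0.16). An earlier time course was examined over 1778 genes called for the day in the other 3 cultures. At 3 days the wild-type male culture was shifted towards their 7-day side by a median of 0.34 (interquartile range 0.72), with 75.5% of the genes on that side. The shift was 0.48 for genes that rose and 0.17 for genes that fell. This cannot decide the question: the 3-day control arrays that chose the genes were also in the reference, which favours such a shift. From 3 to 7 days the wild-type male culture changed by a median of 0.12 on these genes. On the second principal component it lay within the range of the other cultures at 3 days and below their range at 7 days. An earlier time course is argued against for the matrix genes, whose list mean changed by -0.0236 from 3 to 7 days in the other cultures. With a single wild-type male culture, a difference between flasks, litters or animals stays open.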
